A study of Mus musculus with 32 samples.

How the data were processed

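Gene expression was measured in peripheral lymph nodes, mesenteric lymph nodes, spleen and thymus of female C57BL/6 mice aged 12 weeks. The transgenic mice carried CD30 ligand (CD30L, gene symbol Tnfsf8) under a promoter for T cells, and their non-transgenic littermates, called wild type here, were the controls. Each genotype had 4 mice and each mouse gave all 4 tissues, so the series holds 32 arrays, 8 per tissue. Per the labels' protocols, total RNA was isolated with a spin column kit and 5 µg was labelled with biotin for an Affymetrix array. The labels do not say whether mouse numbers of the 2 genotypes share a litter, cage or day.

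The deposited values were intensity values on a linear scale for 45101 probe sets per array. Judged from the values themselves, some background or mismatch signal was subtracted, since 14.9% to 18.4% of the values on each array were negative. The algorithm, its software and any scaling between arrays are not given in the sources used here. The trimmed mean intensity, which leaves out 2% of the values at each end, ran from 106 to 273 over the 32 arrays, a ratio of 2.58, so the deposited arrays were not at a common level. Correlations between the 8 arrays of a tissue lay between 0.913 and 0.985. For arrays there is no read depth, and the number of mice limits the precision.

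From these intensities, negative values were set to 0, 16 was added and log2 was taken. The 8 arrays of a tissue were then brought to 1 distribution by quantile normalization, a choice a rule written beforehand made from the spread of the trimmed means. After 64 control probe sets were left out, probe sets with a mean above the 40th percentile of the tissue were kept, which left 27022 per tissue. Gene symbols came from the annotation table of the array, checked against gene identifiers of the GRCm38.p6 annotation, which matched for 34754 of 34958 probe sets with a single identifier. No coordinates were used, and that annotation served only for names and for the order of neighbouring genes. Of the 45037 probe sets used, 34945 had 1 symbol, 932 had several and 9160 had none in the table used here. For gene lists, each gene was represented by its probe set with the highest mean over the 32 arrays.

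Each tissue was fitted on its own with limma 3.58.1 in R 4.3.3, transgenic against wild type, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Differences between tissues in the transgenic effect were tested with limma on each mouse's difference of log2 values between 2 tissues. The test of 49 gene lists used camera with its preset correlation of 0.01, adjusted over the lists with at least 5 measured genes. Of the 914 list entries 803 matched a measured symbol. Beside it stand camera with a correlation estimated from the data, fry, and an exact permutation test of the list's mean per array, whose smallest p with 4 against 4 mice is 0.0286. Counts "adjusted over the list alone" used the limma p of the members of that list only. Correlations of effects between tissues were set against 34 other splits of the same mice after the genotype means were taken out, since the tissues share their animals.

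The genes named were chosen by a rule. It takes Tnfsf8 and its receptor Tnfrsf8 in every tissue, and the 10 largest rises and 10 largest falls past the threshold whose 4 transgenic arrays lie apart from the 4 wild type arrays. It adds up to 4 members with the smallest p from each list called, up to 3 from lists described but not called, and the 5 smallest p for each difference between tissues. Called probe sets without a representative role, or without a symbol, are also named where a tissue has few calls, and these were chosen after their values were seen.

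The grouping, tests, lists, naming rule and first set of alternatives were chosen before the data were examined. Those alternatives were pseudocounts of 1 and 64, no normalization or a common median, no filter or a filter at the 60th percentile, a fold threshold of 1.5, 1 fit over all arrays and array weights. The others were an intensity trend with robust moderation, a block for mouse number, other list tests, another probe set per gene and leaving out each array. Others were added after seeing the data: leaving out arrays with pancreas, muscle or 3'-biased transcripts, the exact permutation test of lists, and each mouse's mean over its 4 tissues. The block for mice 1 and 2 against mice 3 and 4 rests on a division that was found in the data.

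The limma tests within and between tissues and camera were tested on simulated data made from the real means and spreads, with 50 probe sets changed at each of 4 sizes. The noise was drawn independently for each probe set and array, without correlation between genes or a structure among the mice. The simulation therefore cannot show how camera behaves on lists of correlated genes. The mean over 4 tissues, the exact permutation and the correlations were not tested so. In peripheral lymph node, 72% of the changes of log2 size 1 were recovered and 92% of those of size 2. In mesenteric lymph node the shares were 54% and 92%, in spleen 60% and 94%, and in thymus 64% and 96%. Changes of log2 size 0.5 were recovered for 16%, 22%, 10% and 20% in the same order of tissues. The simulated tissues gave 140 to 150 calls and the real ones 0 to 10, so the adjusted threshold was easier to pass in the simulation. These shares can therefore overstate the recovery in the real data. Of simulated lists shifted by 0.3, 9 of 10 were recovered in peripheral lymph node, 9 of 9 in mesenteric lymph node, 8 of 9 in spleen and 9 of 9 in thymus. For the difference of effects between spleen and thymus, 26% of size 1 and 78% of size 2 were recovered. Among the calls, 11 of 150 in peripheral node and 8 of 140 in mesenteric node were unchanged probe sets. In spleen these were 14 of 142 and in thymus 7 of 146. They were 5 of 107 for spleen against thymus and 13 of 99 for mesenteric node against spleen. Of the lists called, 1 of 12, 0 of 9, 1 of 11 and 2 of 11 held no shifted gene, in the same order of tissues.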

Results

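The data are 32 arrays of 4 lymphoid tissues from 4 CD30L transgenic mice and 4 wild type littermates. The transgene was meant to place CD30L, a member of the TNF family and the ligand of CD30, on T cells, to learn what carrying it changes in living animals. The comparison made in each tissue was transgenic against wild type, and differences of that effect between tissues were tested within mice. Some arrays carried transcripts of neighbouring tissue. In mesenteric lymph node, the exocrine pancreas list mean reached 5.08 (log2, centred per tissue) in wild type mouse 2 and 4.27 at most in the transgenic arrays, against -2.83 and -2.71 at the lowest. In peripheral lymph node, the skeletal muscle list mean ran from -1.18 to 3.15 in wild type and from -1.22 to 0.76 in transgenic arrays. The 3' to 5' ratio of Actb, a measure of RNA integrity, lay between 2.83 and 3.58 in spleens of mice 1 and 2 of both genotypes, and between 1.65 and 1.85 in spleens of mice 3 and 4. In thymus, transgenic mice 1 and 2 had the highest ratios, 2.25 and 2.23. Rag1 and Dntt, genes of lymphocyte precursors, reached 9.30 and 8.43 (log2) in the spleen of wild type mouse 4, where the means of the 8 spleens were 5.30 and 5.71.

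Tnfsf8, the gene for CD30L, showed no difference between genotypes in any tissue by limma. Its log2 fold changes were 0.01 ± 0.09 (SE, n = 4 per genotype) in peripheral lymph node, -0.06 ± 0.13 in mesenteric lymph node, 0.07 ± 0.10 in spleen and -0.10 ± 0.21 in thymus, with adjusted p of 0.984, 0.982, 0.893 and 0.932. Its transgenic values lay between 5.39 and 6.87 on the log2 scale and its wild type values between 6.05 and 6.71. Such arrays carry probes towards the 3' end of the natural transcript, and the sources used here do not say whether the transgene contains that part. The probe set therefore checks neither the labels nor the expression of the transgene. Tnfrsf8, the gene for CD30, had log2 fold changes of -0.20, -0.12, -0.02 and 0.04 in the same order, none past the threshold (adjusted p = 0.788, 0.972, 0.986 and 0.954).

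**Figure D1:**
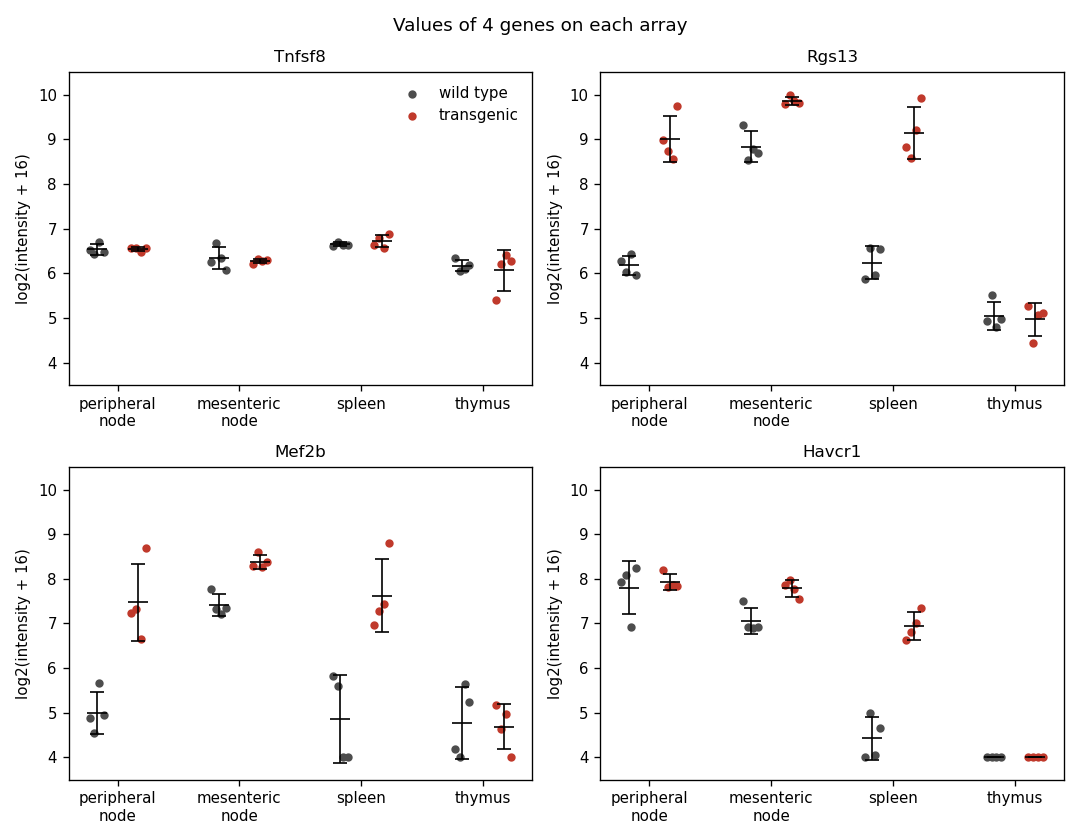
Log2 intensity (after adding 16) of Tnfsf8, Rgs13, Mef2b and Havcr1 on each array by tissue, grey for wild type and red for transgenic, with the mean and SD of each group of 4 mice in black. Tnfsf8 overlaps between genotypes in every tissue, whereas the 4 transgenic values of Rgs13 in peripheral lymph node start at 8.57 and the wild type values end at 6.43.

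In transgenic peripheral lymph nodes, Rgs13, a regulator of G protein signalling expressed in germinal centre B cells, rose 7.11-fold (log2 fold change 2.83 ± 0.25, SE, n = 4 per genotype, adjusted p = 0.0206). The list of germinal centre B cell genes rose with it, with a median log2 fold change of 0.52 over 16 genes, and the cell cycle list with 0.59 over 28 genes (adjusted p = 0.279 with an estimated correlation for both). Plasma cell genes (median 0.23, 24 genes) and immunoglobulin genes (median 1.26, 7 genes) also rose (adjusted p = 0.279 with an estimated correlation for both). Genes common to all T cells fell by a median of 0.19 (16 genes, adjusted p = 0.527 with an estimated correlation), with a mean of 0.00 in place of -0.16 in the values as deposited.

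Of the 28 cell cycle genes, 25 rose when adjusted over the list alone and 0 over all genes, where 1 fit over all 32 arrays called 13. Nusap1, which bundles spindle microtubules, had a log2 fold change of 0.97 ± 0.15. The kinase Cdk1 stood at 1.10 ± 0.18, the proliferation marker Mki67 at 1.33 ± 0.24 and the spindle motor Kif11 at 0.95 ± 0.17, and the transgenic values of all 4 lay above the wild type values. Of the 16 germinal centre genes, 10 rose adjusted over the list alone and 1, Rgs13, over all genes, with 6 called by the fit over all arrays. Mef2b, a transcription factor of germinal centre B cells, had 2.47 ± 0.41 and Mybl1, another, 1.76 ± 0.29, which a pseudocount of 64 lowered to 1.51 and 1.06. Ube2c, a mitotic ubiquitin conjugating enzyme, had 0.93 ± 0.16. Hmmr, Ube2c and Aurka in this list serve mitosis, and the median of the other 13 genes was 0.37. In the plasma cell list 3 genes rose adjusted over the list alone and 0 over all genes. Among its members Eaf2, an elongation factor partner, had 1.81 ± 0.27, Jchain, which joins IgM and IgA polymers, 0.97 ± 0.21, and Slpi, a secreted protease inhibitor, 2.51 ± 0.60. For the immunoglobulin list the counts were 4 and 0, with Iglv1 at 1.26 ± 0.16, Igha at 1.64 ± 0.36, Ighg3 at 1.99 ± 0.54 and Igk at 1.55 ± 0.47. For the pan T cell list both counts were 0. Its members Lat, Cd247, Cd3e and Cd8a had log2 fold changes of -0.26, -0.28, -0.23 and -0.26.

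The labels name no rounds, but mice 1 and 2 are taken apart from mice 3 and 4 because their spleens differed in RNA integrity. In these 2 rounds the mean shift in peripheral lymph node was 0.56 and 0.80 for the cell cycle list. It was 0.74 and 0.89 for germinal centre, 0.45 and 0.44 for plasma cell, 1.03 and 0.96 for immunoglobulin and -0.18 and -0.13 for pan T cell genes. The transgenic and wild type means of these 5 lists did not overlap (exact permutation p = 0.0286, the smallest this design allows). The camera adjusted p was 4.47e-31 for cell cycle, 2.01e-16 for germinal centre, 2.01e-09 for plasma cell, 7.5e-08 for immunoglobulin and 0.00017 for pan T cell genes. All 5 calls were lost with an estimated correlation, at adjusted p = 0.279 for the first 4 and 0.527 for pan T cells with an estimated correlation. The other lists called were MHC class II (median 0.06, led by Ciita, its transactivator, at 0.60 ± 0.13) and neutrophil genes (0.24) upward, and skeletal muscle (-1.39) and reticular stroma (-0.13) downward. Adjusted over the list alone, 1 MHC class II gene rose and 0 genes of the other 3, with 0 over all genes in each. Their camera adjusted p was 0.0273, 0.0459, 0.00626 and 0.0366 and, in that order, adjusted p = 0.385, 0.971, 0.971 and 0.971 with an estimated correlation. Without the 3 arrays with the most muscle transcripts, neutrophil, MHC class II and skeletal muscle genes were not called (adjusted p = 0.899, 0.426 and 0.890), nor was MHC class II with a common median (0.547) or as deposited (0.542). These 4 calls also hung on single arrays. MHC class II was lost without transgenic or wild type mouse 1 (highest adjusted p 0.156), and neutrophil without transgenic mouse 1 or wild type mice 2, 3 or 4 (0.758). The neutrophil mean was 0.02 without transgenic mouse 1, in place of 0.30 with all arrays. Skeletal muscle was lost without wild type mouse 1 or 3 (0.416), and stroma without wild type mice 1 or 4 or transgenic mice 3 or 4 (0.256). The skeletal muscle mean was -0.42 without wild type mouse 1 and -0.11 without the 3 muscle arrays, in place of -1.31. In the values as deposited the stroma mean changed from -0.14 to 0.0350.

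Over all genes, 10 of 27022 probe sets passed the limma threshold in peripheral lymph node, 9 higher and 1 lower in transgenic mice, and 2259 had an unadjusted p under 0.05 where 1351 are expected by chance. The single fit over all 32 arrays called 122, among them Mki67 (adjusted p = 0.000631), Cdk1 (0.000861) and Kif11 (0.00388). The genotypes did not overlap for 5.35% of probe sets, against 2.86% by chance. Besides Rgs13, 4 probe sets of Ighm, the IgM heavy chain, rose by 2.51 to 3.38, chosen after their values were seen. The representative Ighm probe set stood at 0.28 ± 0.15 (adjusted p = 0.673). Probe sets of this gene family can bind transcripts of related heavy chains, so which isotype rose is uncertain. Dtl, which directs replication proteins to degradation, rose by 1.79 ± 0.19 (adjusted p = 0.0289), although 4 other Dtl probe sets had values between -0.30 and 0.53. Adam15, a membrane metalloproteinase, rose by 0.77 ± 0.08 (adjusted p = 0.0289), and Slc39a13, a zinc transporter, fell by 2.74 ± 0.31 (adjusted p = 0.0335). A Poc1b probe set (0.68 ± 0.08) and a probe set without a gene symbol (3.19 ± 0.22) also rose. The count fell to 2 without transgenic mouse 1, 1 without transgenic mouse 2, 2 without transgenic mouse 4, 1 without wild type mouse 1, 3 without wild type mouse 2 and 0 without wild type mouse 4. Leaving out transgenic mouse 1 or 2 or wild type mouse 1, 2 or 4 gave Rgs13 a log2 fold change of 2.76 to 2.92 with adjusted p up to 0.126. The Rgs13 call was also lost without a filter (adjusted p = 0.0770) and with the mouse number as a block (0.182). Without the 3 arrays with the most muscle transcripts it stood at 3.01 (adjusted p = 0.253). Adam15 lost its call when any 1 of the 8 arrays was left out (adjusted p up to 0.163), Dtl for each of 7 arrays (up to 0.131), while without transgenic mouse 4 it was removed by the filter, and Slc39a13 for each except transgenic mouse 1 (up to 0.190). With mice 1 and 2 against mice 3 and 4 as a block, Dtl, Adam15 and Slc39a13 lost their calls (adjusted p = 0.0548 each). The sizes depend on the pseudocount: Dtl stood at 2.80 with a pseudocount of 1 (adjusted p = 0.106) and 0.91 with 64, and Slc39a13 at -3.72 with 1 (adjusted p = 0.161) and -1.71 with 64.

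**Figure D2:**
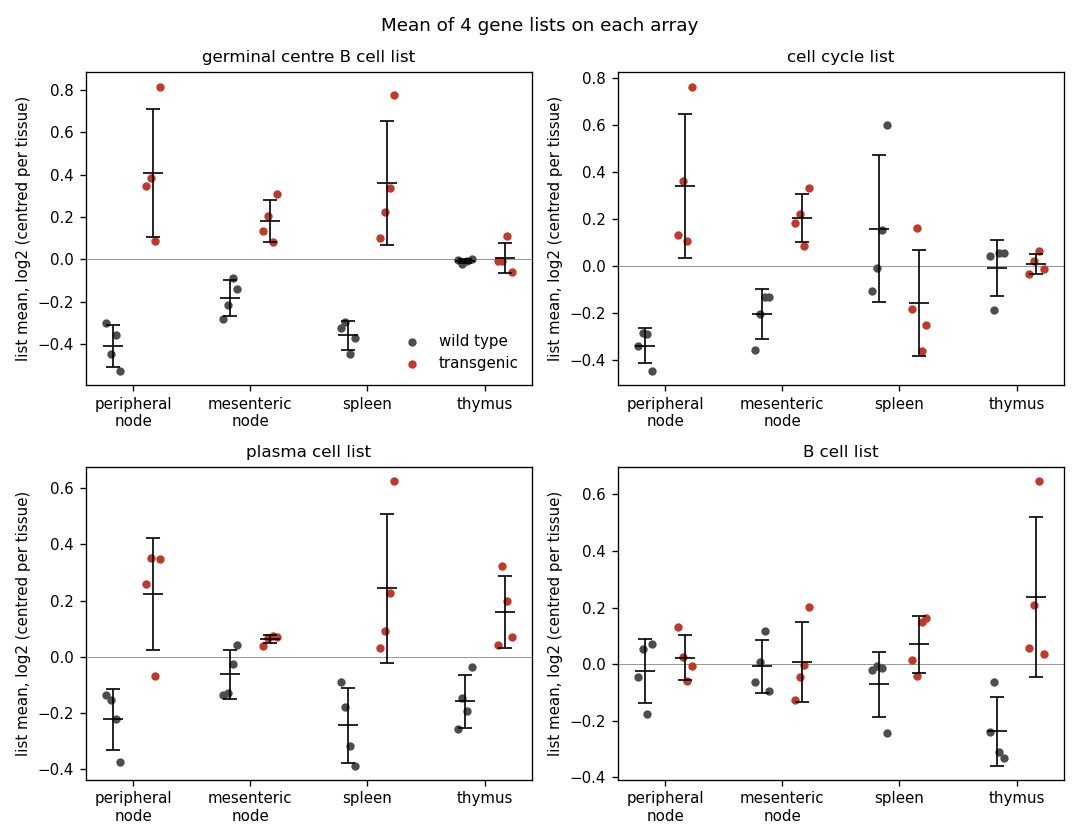
Mean log2 value of 4 gene lists on each array, centred per tissue, grey for wild type and red for transgenic, with the mean and SD of each group of 4 mice in black. For germinal centre genes in peripheral lymph node the transgenic arrays lie between 0.09 and 0.81 and the wild type arrays between -0.52 and -0.30, whereas in thymus the genotypes overlap.

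In transgenic mesenteric lymph nodes the cell cycle list rose, with a median log2 fold change of 0.44 over 28 genes, and the germinal centre list rose with a median of 0.33 over 16 genes (adjusted p = 0.304 with an estimated correlation for both). Glycolysis genes (median 0.13), plasma cell genes (0.07) and genes of activated or memory T cells (0.24) also rose (adjusted p = 0.306 with an estimated correlation for each). Genes of reticular stroma fell by a median of 0.13, naive T cell genes by 0.13, complement genes by 0.09 and macrophage genes by 0.09, with adjusted p = 0.426, 0.470, 0.363 and 0.306 with an estimated correlation. In the values as deposited the means of stroma, complement and macrophage genes turned positive (0.0272, 0.0410 and 0.0174 in place of -0.11, -0.09 and -0.10), and naive T cell genes came to -0.0185 in place of -0.17, all 4 without a call. With a common median the naive T cell (-0.0750, adjusted p = 0.175), macrophage (0.0745) and complement lists (0.146) were not called either.

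Of the 28 cell cycle genes 24 rose adjusted over the list alone and 0 over all genes. Cdc20, an activator of the anaphase promoting complex, had 0.80 ± 0.13 (SE, n = 4 per genotype), the helicase subunits Mcm5 and Mcm2 0.46 ± 0.08 and 0.48 ± 0.10, and the mitotic cyclin Ccnb2 0.63 ± 0.13. Of the 16 germinal centre genes 6 rose adjusted over the list alone and 0 over all genes, with Mef2b at 0.97 ± 0.14, Rgs13 at 1.03 ± 0.17 and Gcsam, a signalling adaptor of germinal centre B cells, at 0.43 ± 0.10. In the plasma cell list 2 rose adjusted over the list alone and 0 over all genes, with Tnfrsf17, a receptor on plasma cells, at 0.77 ± 0.15 (0.51 with a pseudocount of 64) and Eaf2 at 0.51 ± 0.12. The activated T cell list gave the counts 2 and 0. It was led by the chemokine receptor Ccr2 (0.38 ± 0.09), the cytokine receptor Il18r1 (0.36 ± 0.08) and the costimulator Icos (0.30 ± 0.10). Ccr2 is also the 1 gene that rose, adjusted over the list alone, in the macrophage list, whose members C1qa and C1qc, parts of complement C1q, both had -0.27. Adjusted over the list alone 1 complement gene fell, Cd55 (-0.34 ± 0.09), which restrains complement on cell surfaces. Both counts were 0 for glycolysis (Hk2 0.27 ± 0.11), naive T cell (S1pr1 -0.48 ± 0.25) and stroma (Timp3 -0.23 ± 0.11).

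The mean shifts of mice 1 and 2 and of mice 3 and 4 were 0.34 and 0.48 for cell cycle and 0.31 and 0.42 for germinal centre genes, and the genotypes did not overlap for these 2 lists or for glycolysis and macrophage genes (exact permutation p = 0.0286). The camera adjusted p was 3.1e-27 for cell cycle and 3.75e-09 for germinal centre (adjusted p = 0.304 with an estimated correlation for both). For stroma, glycolysis, macrophage, naive T cell, complement, plasma cell and activated T cell lists it was 0.0021, 0.00263, 0.00392, 0.00834, 0.0108, 0.0113 and 0.0292, and adjusted p = 0.426, 0.306, 0.306, 0.470, 0.363, 0.306 and 0.306 with an estimated correlation. Without the 3 arrays with pancreas transcripts, the stroma, macrophage and complement lists were not called (adjusted p = 0.19, 0.076 and 0.21). Of single arrays, leaving out wild type mouse 1 ended the calls of activated T cell, macrophage and complement genes, and wild type mouse 2 those of activated T cell, stroma and complement genes. Wild type mice 3 and 4 each ended those of activated T cell, naive T cell and plasma cell genes, transgenic mice 2 and 3 that of activated T cells, and transgenic mouse 4 those of activated T cell and complement genes. The adjusted p of the calls so lost were 0.0525 to 0.125. Without wild type mouse 2 the stroma mean was -0.03 in place of -0.11 and the complement mean -0.05 in place of -0.09. No probe set passed the threshold over all genes by limma (smallest adjusted p 0.296), while 1274 had an unadjusted p under 0.05 where 1351 are expected. By other fits the count was 3 without a filter and 2 in 1 fit over all 32 arrays.

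In transgenic spleens, Rgs13 rose 7.43-fold (2.89 ± 0.30, SE, n = 4 per genotype, adjusted p = 0.0466), and Havcr1, which encodes TIM-1 on lymphocytes, rose from near the floor (2.52 ± 0.25, adjusted p = 0.0466, and 1.30 with a pseudocount of 64). Genes of follicular helper T cells, the T cells that help germinal centre B cells, rose with a median log2 fold change of 0.57 over 12 genes (adjusted p = 0.295 with an estimated correlation). Germinal centre genes (0.65, 16 genes), plasma cell genes (0.37, 24 genes), regulatory T cell genes (0.40, 19 genes) and pan T cell genes (0.29, 16 genes) also rose, with adjusted p = 0.309, 0.317, 0.295 and 0.295 with an estimated correlation. Erythroid genes fell by a median of 0.80 (19 genes) and those of haem synthesis by 0.74 (10 genes, adjusted p = 0.317 with an estimated correlation for both), while the cell cycle list fell by 0.28 (29 genes, adjusted p = 0.453 with an estimated correlation).

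In the follicular helper list 6 genes rose adjusted over the list alone and 0 over all genes, where 1 fit over all 32 arrays called 5. Pdcd1, which encodes the receptor PD-1, had 1.19 ± 0.19, the transcription factor Tox 1.11 ± 0.18, Icos 0.61 ± 0.15 and the secreted antagonist Sostdc1 1.73 ± 0.46 (0.91 with a pseudocount of 64). In the germinal centre list 9 rose and 1 fell adjusted over the list alone, and 1 rose over all genes, or 8 in the fit over all arrays. Mef2b stood at 2.77 ± 0.54, Basp1 at 0.75 ± 0.15 and Mybl1 at 1.34 ± 0.29. Wild type values of Mef2b lay at the floor on 2 arrays, and its size was 4.88 with a pseudocount of 1 and 1.64 with 64, where Mybl1 had 0.88. In the plasma cell list 8 rose adjusted over the list alone and 0 over all genes, with Eaf2 at 1.16 ± 0.28, Tnfrsf17 at 1.02 ± 0.26 (0.65 with a pseudocount of 64) and Derl3, which helps clear misfolded proteins, at 1.48 ± 0.39. In the regulatory T cell list the counts were 5 and 0. Klrg1, a receptor on differentiated T cells, had 0.79 ± 0.13 and the transcription factor Ikzf2 0.77 ± 0.17. In the pan T cell list they were 5 and 0, with Cd3d at 0.57 ± 0.10 and the kinase Zap70 at 0.59 ± 0.15. The TNF family list rose by a median of 0.27 (adjusted p = 0.295 with an estimated correlation), with counts of 5 and 0, and held Tnfsf11, the ligand RANKL, at 0.79 ± 0.15 (0.43 with a pseudocount of 64) and Tnfsf13b, the B cell survival factor BAFF, at 0.63 ± 0.12. In the haem list 5 fell adjusted over the list alone and 0 over all genes, among them Ppox (-0.97 ± 0.30). In the erythroid list both counts were 0, with Klf1, a transcription factor of red cell precursors, at -1.08 ± 0.38 and Epor, the erythropoietin receptor, at -0.80 ± 0.23. In the cell cycle list both were 0 and all 29 genes had negative values, with Mki67 at -0.43 ± 0.19 and Ccnb2 at -0.61 ± 0.27.

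The spleens of mice 1 and 2 and of mice 3 and 4 differed in RNA integrity, and several shifts differed between these rounds. The mean shift was -0.13 and -1.36 for erythroid genes, -0.18 and -1.30 for haem synthesis and 0.05 and -0.68 for the cell cycle list, so the falls did not hold in both rounds for the cell cycle list. It was 0.47 and 0.96 for germinal centre, 0.37 and 0.83 for follicular helper, 0.20 and 0.78 for plasma cell, 0.23 and 0.50 for regulatory T cell, 0.20 and 0.48 for pan T cell and 0.17 and 0.49 for TNF family genes. These rises, like the erythroid fall, were larger in mice 3 and 4, and whether they are separate from that fall was not tested. The genotypes did not overlap for these last 6 lists (exact permutation p = 0.0286), while erythroid and haem genes had exact permutation p = 0.0571 and cell cycle genes 0.171. The camera adjusted p of plasma cell, erythroid, haem, pan T cell, cell cycle, follicular helper, TNF family, germinal centre and regulatory T cell lists was 3.48e-10, 3.65e-10, 1.03e-07, 1.4e-07, 2.32e-07, 4.54e-07, 1.38e-06, 2.49e-06 and 2.71e-06. None held with an estimated correlation, where in the same order adjusted p = 0.317, 0.317, 0.317, 0.295, 0.453, 0.295, 0.295, 0.309 and 0.295 with an estimated correlation.

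Of the 22 lists called in spleen, 16 rose and 6 fell. Among the other 13, NF-kB target genes rose by a median of 0.22 (Gadd45b 0.63 ± 0.21) and activated T cell genes by 0.29. The rises of mature thymocyte genes (0.15), B cell genes (0.12), glycolysis (0.25), helper 1 and 17 genes (0.32), immunoglobulin (0.21), MHC class I (0.15), cytotoxic (0.08) and thymocyte selection genes (0.08) followed. All these rises were larger in mice 3 and 4 than in mice 1 and 2. In mice 1 and 2 the mean shift was 0.0006 for B cell, 0.03 for glycolysis, 0.03 for cytotoxic and 0.07 for NF-kB target genes. In mice 3 and 4 it was 0.28, 0.36, 0.34 and 0.36. Falls were called for interferon response (-0.23, Oas2 -0.53 ± 0.14), endothelial (-0.14) and exocrine pancreas genes (-0.14, Cela1 -0.52 ± 0.12). Their mean shifts were -0.18, -0.32 and -0.60 in mice 1 and 2 and -0.20, -0.05 and -0.25 in mice 3 and 4. Adjusted over the list alone, 0 NF-kB target, 3 activated T cell, 1 mature thymocyte, 0 B cell, 1 glycolysis, 0 helper, 0 immunoglobulin, 0 MHC class I, 2 cytotoxic and 2 selection genes rose, and 0 interferon, 0 endothelial and 2 pancreas genes fell, with 0 over all genes in each. Their camera adjusted p ran from 6.3e-06 to 0.0265, and adjusted p from 0.295 to 0.533 with an estimated correlation. Without the 4 arrays of mice 1 and 2, whose RNA was less intact, the calls of immunoglobulin (adjusted p = 0.161), MHC class I (0.235), selection (0.0549) and endothelial genes (0.583) were lost. The cytotoxic call was lost with the rounds as a block (0.0545). In the values as deposited the means of B cell, MHC class I and glycolysis genes turned negative (-0.0502, -0.0188 and -0.0033 in place of 0.14, 0.16 and 0.19). Without wild type mouse 4 the calls of cytotoxic, helper, B cell and selection genes were lost, and without wild type mouse 2 those of cytotoxic, immunoglobulin, MHC class I and endothelial genes. Leaving out transgenic mouse 2 ended the calls of selection and endothelial genes, and transgenic mouse 3 that of the cytotoxic list. Wild type mouse 3 ended that of the interferon list and wild type mouse 1 that of the pancreas list. The adjusted p of the calls so lost were 0.0568 to 0.437. Such a loss need not mean that 1 mouse held the shift. The selection mean was 0.22 with all arrays and 0.22 without transgenic mouse 2. The pancreas mean was -0.08 without wild type mouse 1, in place of -0.43.

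Over all genes, 3 probe sets passed the limma threshold in spleen, all higher in transgenic mice, and 2312 had an unadjusted p under 0.05. The single fit over all 32 arrays called 208, among them Tox (adjusted p = 0.00122), Pdcd1 (0.00224) and Mef2b (0.00256). Besides Rgs13 and Havcr1, the third of the 3 probe sets was the one without a symbol that also rose in peripheral lymph node (3.27 ± 0.33), chosen after its values were seen. The genotypes did not overlap for 4.88% of probe sets, against 2.86% by chance. The count was 0 with mice 1 and 2 against mice 3 and 4 as a block and 0 without the 4 arrays of mice 1 and 2, where Rgs13 stood at 3.27 (adjusted p = 0.179) and Havcr1 at 2.78 (adjusted p = 0.179). Leaving out transgenic mouse 2, 3 or 4 gave 0 and wild type mouse 1, 3 or 4 gave 1. Rgs13 lost its call when any 1 of the 8 arrays was left out (2.65 to 3.08, adjusted p up to 0.188) and Havcr1 without wild type mouse 1, 3 or 4 (2.35 to 2.61, adjusted p up to 0.180). Without any 1 of the transgenic mice Havcr1 was removed by the filter, so its call held only without wild type mouse 2.

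In transgenic thymus, B cell genes rose with a median log2 fold change of 0.45 over 18 genes, and all 18 had positive values (adjusted p = 0.3 with an estimated correlation). Reticular stroma genes rose by a median of 0.25 (24 genes), and regulatory T cell and interferon response genes each by 0.23 (18 and 21 genes), with adjusted p = 0.3, 0.3 and 0.339 with an estimated correlation. Genes of immature thymocytes fell by a median of 0.08 (24 genes) and pan T cell genes by 0.11 (16 genes), with adjusted p = 0.193 and 0.356 with an estimated correlation.

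Adjusted over the list alone, 4 B cell genes rose and 0 over all genes. The kinase Blk had 0.98 ± 0.18 (SE, n = 4 per genotype), the IgM receptor Fcmr 0.94 ± 0.24, the antigen receptor chain Cd79a 0.90 ± 0.26 and the adaptor Blnk 0.59 ± 0.18. In the regulatory T cell list 3 rose adjusted over the list alone and 0 over all genes. Capg stood at 0.46 ± 0.11, Tnfrsf4, which encodes OX40, at 0.43 ± 0.12, Klrg1 at 0.78 ± 0.23 and Foxp3, the transcription factor that defines these cells, at 0.37 ± 0.13, the last 2 at 0.43 and 0.20 with a pseudocount of 64. Both counts were 0 for stroma (Madcam1 0.33 ± 0.09, 0.19 with that pseudocount, Col6a2 0.33 ± 0.10), interferon (Ifi27l2a 0.48 ± 0.11), immature thymocyte (Endou -0.17 ± 0.08) and pan T cell genes, where Cd2 (0.22 ± 0.08) went against the list and Cd247 (-0.16 ± 0.07) with it. Further rises, none of which held with an estimated correlation (adjusted p = 0.3 to 0.619), were called for MHC class II (median 0.18), megakaryocyte (0.19), NF-kB target (0.13, Relb 0.47 ± 0.12), plasma cell (0.23, Slpi 2.24 ± 0.48), adipocyte (0.39), MHC class I (0.18), glycolysis (0.11), lymphoid chemokine (0.20, Ccl8 0.78 ± 0.16) and dendritic cell genes (0.19). Of these, adjusted over the list alone, 2 megakaryocyte, 1 plasma cell and 1 chemokine gene rose and 0 of the others, with 0 over all genes. The germinal centre and cell cycle lists were not called in thymus (adjusted p = 0.655 and 0.781). Their medians were both 0.02, their means 0.01 and 0.02, and the test put both downward.

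The mean shift of mice 1 and 2 and of mice 3 and 4 in thymus was 0.66 and 0.29 for B cell genes, 0.29 and 0.20 for stroma, 0.26 and 0.22 for interferon, 0.33 and 0.22 for regulatory T cell, -0.04 and -0.07 for immature thymocyte and -0.08 and -0.07 for pan T cell genes. For adipocyte genes it was -0.0032 and 0.89, so that rise was absent in mice 1 and 2. The exact permutation p was 0.0286 for B cell, stroma and regulatory T cell genes, 0.0857 for interferon and pan T cell genes and 0.0571 for immature thymocyte genes. The camera adjusted p was 3.33e-07 for B cell, 7.75e-06 for stroma, 0.000193 for interferon, 0.00029 for regulatory T cell, 0.000524 for immature thymocyte and 0.00112 for pan T cell genes. In this order adjusted p = 0.3, 0.3, 0.339, 0.3, 0.193 and 0.356 with an estimated correlation. Without transgenic mice 1 and 2, whose 3' to 5' ratios were highest, the megakaryocyte (adjusted p = 0.0782) and MHC class I calls (0.0506) were lost. With the values as deposited and with a common median, MHC class I (0.334 and 0.285) and glycolysis (0.307 and 0.116) were not called. With the values as deposited, dendritic cell (0.0870) and MHC class II genes (0.110) were not called either. Without transgenic mouse 4, only 7 lists were called, and NF-kB target, plasma cell, dendritic, MHC class I, MHC class II, chemokine, adipocyte and glycolysis genes lost their call. Leaving out wild type mouse 2 ended the calls of dendritic, MHC class I, chemokine, adipocyte and glycolysis genes. Wild type mouse 3 ended those of NF-kB target, dendritic and chemokine genes, and transgenic mouse 3 those of dendritic, adipocyte and glycolysis genes. Wild type mouse 1 ended that of MHC class I, wild type mouse 4 that of adipocyte and transgenic mouse 1 that of dendritic genes. The adjusted p of calls so lost ran up to 0.298. A lost call does not mean that 1 mouse held the shift. The adipocyte mean was 0.45 without wild type mouse 2 and 0.25 without transgenic mouse 3.

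Over all genes, 1 probe set passed the limma threshold in thymus, which has no gene symbol (1.99 ± 0.14, adjusted p = 0.00918), chosen after its values were seen. At an unadjusted p under 0.05 there were 1962, and 1 fit over all 32 arrays called 48. The genotypes did not overlap for 4.61% of probe sets, against 2.86% by chance. The count was 0 when transgenic mouse 1, 2, 3 or 4 or wild type mouse 1 or 3 was left out, and 2 without wild type mouse 2 or 4.

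The transgenic effect differed between spleen and thymus for 2 of 29255 probe sets by limma within mice. Rgs13 differed by 2.97 ± 0.26 (adjusted p = 0.0267), and Tubb4a, a beta tubulin, by 2.91 ± 0.20 (adjusted p = 0.00532) with 3.00 in spleen and 0.08 in thymus. Rgs13 lost this call without wild type mouse 1, 2, 3 or 4 or transgenic mouse 2 or 3 (adjusted p up to 0.216), and Tubb4a without wild type mouse 2 or 4 (adjusted p up to 0.0515). The Rgs13 difference was also not called with a pseudocount of 1 (adjusted p = 0.218), without a filter (0.0986) or with an intensity trend (0.0520). For the other 5 pairs of tissues the count was 0, with 1524 probe sets at an unadjusted p under 0.05 between the 2 lymph node sites, 2181 between peripheral node and spleen and 2811 between peripheral node and thymus. There were 1741 between mesenteric node and spleen and 1428 between mesenteric node and thymus. A fit that leaves out which tissues came from 1 mouse gave 7, 2, 7, 1 and 0 in this order.

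Some lists went opposite ways in different tissues and differed by a test of the difference. The cell cycle shift was higher in peripheral node than in spleen by 0.99 (camera adjusted p = 1.4e-27, adjusted p = 0.305 with an estimated correlation) and higher in mesenteric node than in spleen by 0.73 (2.86e-24, adjusted p = 0.326 with an estimated correlation). The germinal centre list rose more in peripheral than in mesenteric node by 0.45 (3.21e-08, exact permutation p = 0.0286), and more in peripheral node than in thymus by 0.81 (1.38e-12, exact permutation p = 0.0286). Between peripheral node and spleen its shift differed by 0.10 (camera adjusted p = 0.659, exact permutation p = 0.486). In wild type mice Rgs13 stood at 8.53 to 9.33 in mesenteric and 5.96 to 6.43 in peripheral node (log2). The smaller rise in mesenteric node thus began from a higher level for this gene. Pan T cell genes rose in spleen and fell in peripheral node, with a peripheral node minus spleen difference of -0.50 (camera adjusted p = 1.48e-10, adjusted p = 0.305 with an estimated correlation). Whether the rise of pan T cell genes in spleen is separate from the fall of erythroid genes there was not tested. No list difference held with an estimated correlation, where the smallest adjusted p was 0.284.

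Across genes, the effects in peripheral and mesenteric lymph node correlated with Pearson r = 0.20 and Spearman rho = 0.15 over 12813 genes, which are not independent replicates. Other splits of the same mice gave r between -0.14 and 0.31 with a mean of 0.08, so by these splits the observed value is not outside what shared animals give. Its covariance was 0.00848, against 0.00243 in those splits. With mice 1 and 2 for 1 tissue and mice 3 and 4 for the other, r was 0.20 and 0.15. Shared animals cannot give these 2 values, since the tissues had no mouse in common. Over the remaining pairs of tissues such values ran from -0.16 to 0.15. For the other pairs r was 0.09 (peripheral node and spleen), 0.00 (peripheral node and thymus), 0.08 (mesenteric node and spleen), 0.06 (mesenteric node and thymus) and 0.06 (spleen and thymus), each inside the range of its other splits. At an unadjusted p under 0.05, 165 genes were higher in transgenic mice in both lymph node sites, where independent lists would share 16.3. In 18 splits of the same mice with both genotypes on each side, added after seeing the data, up to 56 genes were shared in 1 direction, the highest for mice 1 and 2 against mice 3 and 4. The excess over either number is not taken as a shared effect.

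The mean of each mouse's 4 tissues, an addition made after seeing the data, asks which genes differed between genotypes on average over the tissues, and a single tissue can carry such a call. By limma 19 of 28029 probe sets passed the threshold, 18 higher and 1 lower in transgenic mice. Rgs13 (1.67 ± 0.13, SE, n = 4 per genotype) and Mef2b (1.53 ± 0.14) were among them, with -0.08 each in thymus. Tubb4a was called with -0.17, 0.04, 3.00 and 0.08 in peripheral node, mesenteric node, spleen and thymus. Acsl6, an enzyme that activates fatty acids, was higher by 1.51 ± 0.12 (adjusted p = 0.00352), and ranged from 1.25 in mesenteric node to 1.75 in spleen (Acsl6 with a pseudocount of 64 ranged from 0.64 to 0.94). The neighbouring genes Vps54, Ugp2 and Mdh1 on chromosome 11 were also among them, with adjusted p from 0.00567 to 0.0409 over their called probe sets. Vps54 serves vesicle transport, Ugp2 makes UDP-glucose and Mdh1 is the cytosolic malate dehydrogenase. The representative probe sets of Vps54, Ugp2 and Mdh1 had means of 0.58, 0.56 and 0.26, and the mean of these 3 was 0.47 in peripheral node, 0.40 in mesenteric node, 0.49 in spleen and 0.51 in thymus, with all transgenic mice above all wild type mice in each tissue (exact permutation p = 0.0286). These 3 genes were chosen after their values were seen. The count of 19 became 12 without wild type mouse 2 and 10 without wild type mouse 4.

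**Figure D3:**
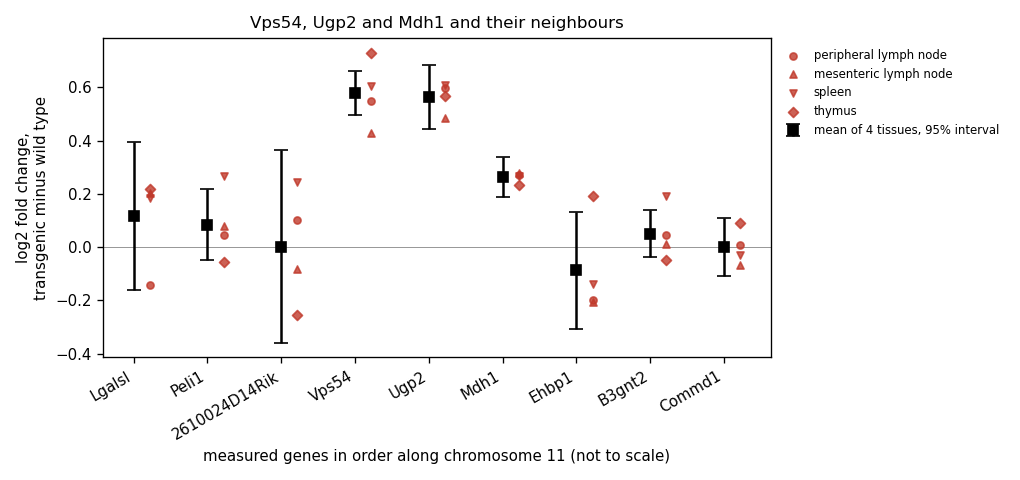
Log2 fold change, transgenic minus wild type, of Vps54, Ugp2, Mdh1 and 3 measured genes on each side in their order along chromosome 11 (not to scale), as the mean of 4 tissues with its 95% interval (black) and each tissue (red). The 3 genes lie between 0.26 and 0.58, and the intervals of the other 6 include 0.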

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

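In this part, the exact permutation test of list means and the 18 splits within rounds were chosen only after the data were seen, and the cell cycle pattern had been noticed before its tests were written. In 186 groups of 4 arrays, 12 values stood far from the other 3 arrays of their group, where chance gives about 1 in 20 groups, or 9.3. In peripheral lymph node, transgenic mouse 3 had a trimmed mean intensity of 268 where the other 3 lay between 218 and 224, and transgenic mouse 4 had a 3' to 5' ratio of Gapdh of 1.69 against 1.27 to 1.33. Transgenic mouse 1 had a skeletal muscle list mean of 0.76 in the same tissue, against -1.22 to -0.94. In mesenteric lymph node, transgenic mouse 1 had a 3' to 5' ratio of 3.10 for Actb (others 1.59 to 1.75) and 2.18 for Gapdh (others 1.25 to 1.30), with an adipocyte list mean of 0.49 (others -0.22 to -0.16). Transgenic mouse 3 stood low for the plasma cell list at 0.0399 against 0.0683 to 0.0724, and wild type mouse 2 high for exocrine pancreas at 5.08 against -2.83 to -2.66. In spleen, transgenic mouse 4 had a regulatory T cell list mean of 0.31 (others 0.12 to 0.15). Wild type mouse 4 stood low in spleen for B cell genes at -0.24 and for mature thymocyte genes at -0.22, and that array also had the highest Rag1 and Dntt of the 8 spleens, at 9.30 and 8.43 (log2), genes of lymphocyte precursors. In thymus, wild type mouse 3 had an exocrine pancreas list mean of -0.20 against 0.00 to 0.03 for the others.

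In 7 list comparisons the shifts called went in opposite directions between tissues, and the genotypes' within-mouse differences did not overlap. The 7 were picked by a called difference with camera and an exact permutation p under 0.05 (4 against 4 mice). With so few mice that p can only be 0.0286, so it adds no evidence beyond the selection. It is also not corrected for the lists and pairs of tissues searched. The cell cycle list was higher in peripheral node than in spleen by 0.99 and in mesenteric node than in spleen by 0.73. Pan T cell genes differed by -0.50 for peripheral node minus spleen and by 0.42 for spleen minus thymus. Stroma genes differed by -0.43 for peripheral node minus thymus and by -0.40 for mesenteric node minus thymus, and interferon response genes by -0.43 for spleen minus thymus. In the order given, these had adjusted p = 0.305, 0.326, 0.305, 0.310, 0.587, 0.284 and 0.498 with an estimated correlation. For single genes, the effect in spleen exceeded that in thymus by 2.91 for Tubb4a and by 2.97 for Rgs13 (limma, adjusted p = 0.00532 and 0.0267).

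The cell cycle list was lower in transgenic spleen and higher in transgenic lymph nodes, and 2 explanations for the fall in spleen were tested. If fewer erythroid precursors were behind it, the cell cycle and erythroid means of the 8 spleens should move together within genotypes, and Pearson r was 0.762 (permutation p = 0.0156 one-sided and 0.0538 two-sided), rho 0.714 (permutation p = 0.0764) and r without the 2 farthest spleens 0.946. Within genotype and round r was 0.465. If the rounds of mice were behind it, only 1 round should show a fall, and the shift was 0.0469 in mice 1 and 2 and -0.68 in mice 3 and 4. Each round held 2 mice of each genotype, so a plain difference between rounds cannot itself give a difference between genotypes. The values show only that the fall lay in mice 3 and 4, with 2 against 2 mice, and why was not tested. The erythroid explanation is not argued against by these tables and may account for the fall. An effect of the transgene on dividing cells of the spleen stays open as untested.

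For each tissue the 8 mice can be split into 2 groups of 4 in 35 ways, the real one included. In peripheral lymph node only the real split gave 10 probe sets, the highest other split giving 3. That share is under 0.05, but it is the smallest 35 splits allow and is not corrected for the other counts tested so. Chance is therefore not excluded for that count. These splits ignore the 2 rounds of mice, and the 18 that keep 2 mice of each round on both sides (highest other 0) are too few for a share under 0.05. With the rounds as a block the count was 4. In mesenteric node all 35 gave at least the real 0 (highest other 2). In spleen 2 splits gave at least the real 3, and in thymus 4 gave at least the real 1 (highest other 1), so chance cannot be excluded for these 3 tissues. The highest other split in spleen, with 2050 probe sets, was that of mice 1 and 2 against mice 3 and 4, which points to a structure of the samples. With that structure as a block, the spleen count was 0. Of the 18 splits within rounds only the real one gave 3 in spleen (highest other 0), again too few for a share under 0.05. For the number of lists called, 12 splits gave at least the real 9 in peripheral node (highest other 13) and 14 at least the real 9 in mesenteric node (highest other 13). In spleen 2 gave at least the real 22 (highest other 22) and in thymus 3 at least the real 15 (highest other 24), so chance cannot be excluded for any of these numbers of lists. For differences between tissues, 35 splits gave at least the real 0 for each pair other than spleen against thymus. The highest other was 1166 for peripheral node against spleen, again the split of mice 1 and 2 against mice 3 and 4, and 0 or 1 for the other pairs. For spleen against thymus only the real split gave 2 (highest other 1), again the smallest share 35 splits allow. The 18 splits within rounds (highest other 1) are again too few, so chance is not excluded there. With the rounds as a block that count was 3.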

How the results depend on the processing

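The alternatives that left out arrays with muscle, pancreas or 3'-biased transcripts, the exact permutation of list means and the mean of each mouse's 4 tissues were chosen only after the data were seen. Counts of probe sets past the limma threshold were 10 in peripheral lymph node, 0 in mesenteric lymph node, 3 in spleen and 1 in thymus. A pseudocount of 1 gave 0 in spleen and 0 in thymus, and a pseudocount of 64 gave 5 in thymus. The values as deposited, without normalization, gave 112 in peripheral node, 5 in spleen and 4 in thymus. There the median of all genes moved by 0.18 in peripheral node and -0.17 in spleen, to which these changes are relative. A common median gave 0 in spleen. Without a filter the counts were 6 in peripheral node, 3 in mesenteric node and 5 in thymus, and with a filter at the 60th percentile 0 in thymus. A single fit over the 32 arrays gave 122, 2, 208 and 48 in the 4 tissues. Array weights gave 5 in spleen, and an intensity trend with robust moderation gave 18 in peripheral node and 8 in thymus. Without the 3 arrays with the most muscle transcripts 1 was left in peripheral node, without mice 1 and 2 there were 0 in spleen and without transgenic mice 1 and 2 there were 0 in thymus, each with fewer samples. The mean of each mouse's 4 tissues gave 19, set beside each tissue. Except where said, the cause was not tested. Leaving out 1 array at a time gave 0 to 11 in peripheral node, 0 in mesenteric node, 0 to 2 in spleen and 0 to 2 in thymus.

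Whether mouse numbers pair transgenic with wild type mice is not given. Pairs with the same number had correlations of their residual values down to -0.00 in peripheral node, -0.49 in mesenteric node, -0.09 in spleen and -0.07 in thymus, and pairs over 0.1 numbered 2, 1, 3 and 1 of 4. Since not every pair lay over 0.1, the numbers were not taken as pairs. With the mouse number as a replicate block, the count was 2 in peripheral node, 0 in mesenteric node, 0 in spleen and 0 in thymus, with 10, 8, 20 and 17 lists. With mice 1 and 2 against mice 3 and 4 as a block it was 4, 0, 0 and 1, with 9, 9, 22 and 17 lists.

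Lists called numbered 9, 9, 22 and 15 in peripheral node, mesenteric node, spleen and thymus. With an estimated correlation there were 0, 0, 0 and 0, and with fry, over all lists tested, 0, 1, 5 and 7. The exact permutation of list means, unadjusted, was at its minimum for 6, 5, 12 and 9 of all lists tested. Of the lists called by camera, 0, 1, 5 and 5 held with fry and 6, 4, 12 and 7 with the exact permutation. With camera, leaving out 1 array gave 6 to 11, 7 to 13, 18 to 24 and 7 to 21. The median, mean and test of a list differed in sign for 15, 9, 9 and 7 lists, 0 of them called.

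In the values as deposited 8 list means changed sign, where the median of all genes moved by 0.18 in peripheral node, 0.08 in mesenteric node and -0.17 in spleen. In peripheral node stroma became 0.0350 and pan T cell 0.0027. In mesenteric node stroma became 0.0272, complement and pentraxin 0.0410 and macrophage or monocyte 0.0174. In spleen B cell became -0.0502, MHC class I and antigen processing -0.0188 and glycolysis -0.0033. By camera, which tests a list against the other genes, 8 of 9, 5 of 9, 19 of 22 and 11 of 15 list calls held there in peripheral node, mesenteric node, spleen and thymus.

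The transgenic effect differed between peripheral and mesenteric node for 0 probe sets. This became 1 with a pseudocount of 64, 5 as deposited, 1 with the 60th percentile filter, 1 with array weights and 7 without the mouse block. Between peripheral node and spleen 0 became 1 with a pseudocount of 1, 1 as deposited, 2 without a filter, 1 with the 60th percentile filter and 2 without the mouse block. Between peripheral node and thymus 0 became 2 with a pseudocount of 64, 3 as deposited, 2 with a common median, 3 with the 60th percentile filter and 7 without the mouse block. Between mesenteric node and spleen 0 became 1 with a pseudocount of 1, 1 as deposited and 1 without the mouse block, and between mesenteric node and thymus 2 as deposited. Between spleen and thymus 2 became 4 with a pseudocount of 64, 4 without a filter (without Rgs13), 0 with the replicate block, 1 with the trend and 6 without the mouse block. Leaving out 1 mouse gave 0, 0 to 1, 0 to 1, 0, 0 to 1 and 0 to 3 for these 6 pairs. The cause was not tested.

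The correlation of effects across genes moved for several pairs when the 2 tissues came from different mice. For the 2 lymph node sites 0.20 became 0.20 (first tissue from mice 1 and 2) and 0.15 (first tissue from mice 3 and 4). For peripheral node and spleen 0.09 became 0.0667 and 0.0462 in that order. For peripheral node and thymus 0.00 became 0.0661 (first tissue from mice 1 and 2) and -0.16 (first tissue from mice 3 and 4). For mesenteric node and spleen 0.08 became 0.0363 with the first tissue from mice 1 and 2, and for mesenteric node and thymus 0.06 became 0.12 with the first from mice 3 and 4. For spleen and thymus 0.06 became -0.0540 and 0.153 in that order, and -0.0012 without a filter. For single genes and settings, 13526 values kept their side of the threshold, 82 fell short of it, 91 came past it and 170 values of uncalled genes changed sign. For lists 914 calls held, 232 were lost and 8 means changed sign. Values near the floor of log2(16) carry little signal over background, as for Havcr1 in thymus with 4 on every array, and a pseudocount of 64 moved 108 gene values of log2 size over 0.2 by over 1.5 times.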

Other observations

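The mean over each mouse's 4 tissues, the tests of cell composition and of single probe sets for the chromosome 11 genes, the 18 splits within rounds and the test of Glycam1 were chosen only after results were seen. The mean over 4 tissues also called the following genes, of which Csn2, Gh and Hrk are in no list. Csn2, a milk casein, was higher in transgenic mice for both its probe sets (1.01 and 0.54 by limma on the mean of 4 tissues), with 2.11 in spleen and 0.11 in mesenteric node for the first (1.14 in spleen with a pseudocount of 64). Gh, the growth hormone gene, had a mean of 0.83, with 1.68 in thymus and 0.50 to 0.60 in the other tissues (1.03 in thymus with a pseudocount of 64). Whether the transgene carries growth hormone sequence that this probe set detects is not known and was not tested. Klrg1, a receptor of differentiated T and NK cells and a member of the cytotoxic and regulatory T cell lists, had a mean of 0.73, with 0.46 in peripheral node, 0.89 in mesenteric node, 0.79 in spleen and 0.78 in thymus. Hrk, which promotes apoptosis, was the 1 gene lower, with a mean of -0.49, from -0.996 in peripheral node, -0.30 in mesenteric node and -0.82 in spleen, and with 0.16 in thymus the other way. Of the 35 splits of the mice only the real one gave 19 probe sets (highest other 5, the split of mice 1 and 2 against mice 3 and 4). That is the smallest share 35 splits allow, not corrected for the other counts tested so, and chance is not excluded. The 18 splits that keep 2 mice of each round on both sides (highest other 0) are too few for a share under 0.05, and with the rounds as a block the count was 16.

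In thymus, the representative probe set of Ighm stood at -0.15, while the 4 Ighm probe sets that rose in peripheral node stood between 2.24 and 2.83 (adjusted p from 0.604 to 0.613), which misses the threshold. Slpi, a secreted protease inhibitor, stood at 2.51 in peripheral node and 2.24 in thymus, with adjusted p of 0.288 and 0.440. In spleen, Tnfrsf4 had 0.63 and Nt5e, which makes adenosine on regulatory T cells, 0.88, and both lay apart between genotypes without passing the threshold over all genes (adjusted p = 0.528 for both).

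Vps54, Ugp2 and Mdh1, neighbours on chromosome 11, were higher in transgenic mice by a mean of 0.47 (95% interval 0.42 to 0.51, 1.38-fold). Random orders of the genes held a window of 5 neighbours as high as the highest of the real order in 0.17% of 10000 cases, which argues against chance clustering. The 3 genes were higher in 4 of 4 tissues, so no single tissue held the rise. They were chosen by their mean over these tissues, however, and a composition change common to all 4 was not tested. Plasma cell genes also had positive medians in each (0.23, 0.07, 0.37 and 0.23 in peripheral node, mesenteric node, spleen and thymus). All 14 probe sets (100%) rose, among them the called ones by which the genes were chosen. Those not called also rose (limma, unadjusted p up to 0.0217), which argues against a sequence variant under single probe sets. The nearest measured gene on each side had an upper 95% bound of 0.36 at most, and the 3 nearest on each side 0.39 at most, below that mean. This argues against a longer stretch at a like dose, although the representative Mdh1 probe set, at 0.26, lies under these bounds. The other Mdh1 probe sets stood at 0.27, 0.40 and 0.50. Extra copies limited to these 3 genes were not tested. An effect of the transgene's insertion on these genes may account for the pattern, as may DNA of another strain around the insertion, and both stay open as untested.

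The B cell list was higher in transgenic thymus, by a median of 0.45 (adjusted p = 0.3 with an estimated correlation). Lymph node tissue with its high endothelial venules, carried along at dissection, would need a 2.10% share of node RNA and a Glycam1 level of 7.88. The highest of the 8 thymus arrays stood at 4.00, which argues against it on that 1 gene. Follicle and venule genes of lymph nodes together had a median of 0.33. Of those outside the B cell list, Cxcl13 had 0.79, Madcam1 0.33, Fut7, near the floor, 0.25 and Glycam1 0. The venule genes cannot test node tissue without venules, and Cr2, Fcer2a and Cxcr5 also belong to the B cell list. This median therefore decides nothing, and node tissue without venules stays open. A lower share of thymocytes would raise other cell types alike. B cell genes exceeded thymic epithelium by 0.34, endothelial genes by 0.35 and macrophage genes by 0.37 (highest exact permutation p = 0.0571), so that explanation may hold, and more B cells in the transgenic thymus stay open as untested.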
